A study of Mus musculus with 42 samples.

How the data were processed

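The deposited values were the authors' UMI counts, in 42 matrices of genes by barcodes that had already been reduced to called cells. Per the labels, the submitters aligned the reads to mm10 and counted them with Cell Ranger 3.0.1, and worked further in Seurat; 22 matrix headers name that version, 7 name 4.0.0 and 13 name none. The CD45 and AH1 monotherapy matrices used an older, shorter gene annotation than the AH1 combination and Ly6G matrices. The 12 antibody tag features of 7 matrices, and a human VSIR feature with 0 UMIs in 4, were kept out. The tags were not used to assign cells, since the labels give no map from tag to sample; the pooled Ly6G library, whose cells come from 4 arms, was therefore given values only. Groups and replicates were read from the sample titles and characteristics. R and NR are not spelt out in the sources used here.

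Barcodes with under 200 genes or over 10% mitochondrial UMIs were removed, then the likeliest doublets. Each barcode was scored by its share of simulated doublets among its nearest neighbours, in code written here after the idea of Scrublet, and the number of top-scoring barcodes removed grew with library size, so that their percentage was 0.0008 times the number of barcodes. Each dataset was clustered alone with no integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes without antigen receptor and mitochondrial genes, 30 principal components, 15 neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Clusters were named from marker lists fixed before the data were examined, by mean scaled marker score with at least 3 markers detected, and T cells were split by Cd3e, Foxp3, Cd8a, Cd8b1 and Cd4. Ambiguous clusters stayed unnamed. Names are written as "-like" because they rest on transcripts alone.

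Counts were summed per library and class where a library held at least 20 cells of the class, and tested where each group had at least 2 such libraries. The tests used edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test) in R 4.3.3, with a group term and, in the combination arm, an experiment term. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within each comparison and class. Named genes followed a rule fixed before the data were examined: in each main class up to 3 higher and 3 lower genes with the largest change among those that passed, had a mean log2 CPM of at least 4 and lay beyond the other group's mean in every library of the smaller group. Where none passed, the 2 genes with the smallest p were named as not passing. Up to 4 passing members of each gene list and 5 checkpoint genes were added. Antigen receptor, mitochondrial, ribosomal, haemoglobin and provisional gene names were left out. CPM values are scaled by the TMM factors.

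The 17 gene lists, written before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists and classes of a comparison, and again with a correlation estimated from the data ("at estimated correlation") and with fry. The preset correlation understates the spread between libraries, so few calls made with it outlast the estimated one.

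Class shares were compared on the logit scale after adding 0.5 cells, by all exact permutations of libraries within experiments, two-sided, adjusted over classes. CP against untreated shares used experiment 1 alone. Intervals of single-library shares are exact Clopper-Pearson 95% intervals and cover counting error only. Groups of 1 library (both AH1 sorts, the Ly6G sort and monotherapy experiment 1) were described by log2 ratios of CPM with 10 added, for genes of at least 50 CPM in either library, with the 5 highest and 5 lowest genes named. Each list's median was ranked among 10000 random lists matched on expression. In monotherapy experiment 1 the monocyte/macrophage-like and CD8 T-like sums were used, a choice made without seeing their values. The AH1 and Ly6G sums took all kept cells of a library.

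Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, fits with 2 groups, each experiment alone, doublets kept, a filter of 500 genes and 5% mitochondrial UMIs, resolution 2.0 and leaving out each library. Thinning of libraries to equal class totals, and leaving out each library from the type I interferon list score, were added after the data were seen. No scaling alternative moved the median log2 change of all genes by more than 0.1. The test code was checked on simulated data with planted changes: of 2-fold changes it found 79% in CD8 T-like and 86% in monocyte/macrophage-like cells of the monotherapy comparison, and of 4-fold changes 94% and 97%. In Treg-like and neutrophil-like cells it found 52% and 50% of 2-fold changes there, and in neutrophil-like cells of CP against untreated 13% (61% of 4-fold changes), so that few or no calls in those classes say little. No libraries were duplicates (lowest chi-square per degree of freedom between replicates 8.89). Correlations of same-numbered replicates (3 pairs in monotherapy) left pairing open. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.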

Results

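Tumour-infiltrating leukocytes were profiled by droplet single-cell RNA sequencing of 5′ transcript ends in 42 libraries, all from mice carrying CT26, a transplantable colon carcinoma line. The series addresses VISTA (gene Vsir, ENSMUSG00000020101), an inhibitory immune checkpoint, in relation to T cell quiescence and to suppression by myeloid cells. In the monotherapy arm, treatment with anti-VISTA or control IgG began when tumours were small. In the combination arm, treatment of larger tumours began later, with anti-PD-1 plus anti-CTLA4 (CP) or with CP plus anti-VISTA (CPV). The labels mark the CD45 and AH1 libraries of anti-VISTA and CPV tumours as R or NR, read here as responding and non-responding. CP libraries carry no such mark, so CPV R and CPV NR tumours were set against CP tumours not sorted by response. CD45-enriched leukocytes gave 31 libraries. Monotherapy experiment 1 had 1 library each of IgG, anti-VISTA NR and anti-VISTA R, and experiment 2 had 3 IgG and 5 anti-VISTA R libraries. Combination experiment 1 had 3 untreated, 3 CP, 2 CPV NR and 2 CPV R libraries, and experiment 2 had 4 CP, 3 CPV NR and 3 CPV R libraries. CD8 T cells binding the AH1 tetramer, which presents a tumour peptide, gave 8 libraries, and sorted Ly6G-positive myeloid cells gave 3.

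Library totals ran from 9318098 to 92929166 UMIs over 1648 to 10732 barcodes. In monotherapy experiment 2 the IgG libraries held 43178683 to 66779764 UMIs and the anti-VISTA R libraries 55090871 to 92929166. Combination experiment 1 libraries held 18444484 to 33830120 UMIs. In combination experiment 2 the groups differed in depth: the CP libraries held 19054257 to 28188533 UMIs and the CPV libraries 9521446 to 14807697. The lowest UMI total of any barcode was 2238 to 5910 in experiment 1 of either arm and 500 to 507 in experiment 2. Neutrophil-like cells were sparse or unnamed in experiment 1, and whether that floor was the cause was not tested.

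Macrophages of tumours that responded to anti-VISTA alone differed from those under IgG in monotherapy experiment 2, the only replicated anti-VISTA comparison without other antibodies. In monocyte/macrophage-like cells Retnla (ENSMUSG00000061100), a secreted product of alternatively activated macrophages, rose from 59.7 ± 26.4 CPM (SD, n = 3) to 824 ± 227 CPM (SD, n = 5), a log2 change of 3.79 ± 0.35 (SE; edgeR adjusted p = 0.00629). Ltc4s (ENSMUSG00000020377), the synthase of leukotriene C4, rose by 1.58 ± 0.33 (adjusted p = 0.0301), and Tppp3 (ENSMUSG00000014846) by 1.24 ± 0.24 (adjusted p = 0.0237). Igfbp4 (ENSMUSG00000017493) changed by -0.80 ± 0.11 (adjusted p = 0.0118). Plau (ENSMUSG00000021822), the urokinase plasminogen activator, changed by -0.76 ± 0.09 (adjusted p = 0.00711), and Ccl12 (ENSMUSG00000035352), a monocyte-attracting chemokine, by -0.66 ± 0.10 (adjusted p = 0.0151). Each of these 6 genes also lay on its side of the IgG mean in all 5 R libraries. Of 12519 genes tested, 328 rose and 151 fell. The total of 479 was 890 with DESeq2, 184 at resolution 2.0 and 34 with the replicate block. It also hung on single libraries: it was 306, 160 and 9 without IgG replicate 1, 2 or 3, and 265, 815, 144, 153 and 214 without R replicate 1, 2, 3, 4 or 5.

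Cell-cycle genes were lower as a group in the same macrophage-like cells. Of 35 proliferation genes tested, 18 fell and none rose (29 fell when adjusted within the list), among them the mitotic regulators Cdc20 (ENSMUSG00000006398, -0.61 ± 0.10), Ccnb2 (ENSMUSG00000032218, -0.59 ± 0.12) and Ccnb1 (ENSMUSG00000041431, -0.54 ± 0.10). The list's median change was -0.32 (camera adjusted p = 5.83e-28; adjusted p = 0.286 with an estimated correlation). MHC class II presentation genes had a median of 0.31 with 12 of 15 positive (camera adjusted p = 0.000117; adjusted p = 0.638 at estimated correlation), and H2-Eb1 (ENSMUSG00000060586) rose by 0.63 ± 0.14; 7 rose when adjusted within the list. Type I interferon response genes had a median of -0.12 (adjusted p = 0.00178; adjusted p = 0.822 at estimated correlation), and no member passed. Ccl2 (ENSMUSG00000035385) fell by 0.48 ± 0.08 within the inflammatory cytokine list (median -0.09, adjusted p = 0.0454; adjusted p = 0.822 at estimated correlation), its only member past the threshold also when adjusted within the list. The hypoxia and glycolysis list had a median of -0.09 (adjusted p = 0.0118; adjusted p = 0.822 at estimated correlation), with no member past either threshold. Camera called none of the myeloid suppression (median 0.12, adjusted p = 0.0631), interferon-gamma response (0.04, 0.679), complement and scavenger macrophage (-0.03, 0.861) and inflammatory monocyte lists (0.07, 0.861), the test's direction being opposite to the median for the last pair. Cebpb (ENSMUSG00000056501), a myeloid transcription factor on the suppression list, rose by 0.57 ± 0.12, and Mertk (ENSMUSG00000014361), a receptor for apoptotic cells on the complement and scavenger list, by 0.41 ± 0.07. Markers of cDC2, a dendritic cell class, were also higher in these sums (median 0.25 over 10 genes, 2 of them past the threshold).

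**Figure D1:**
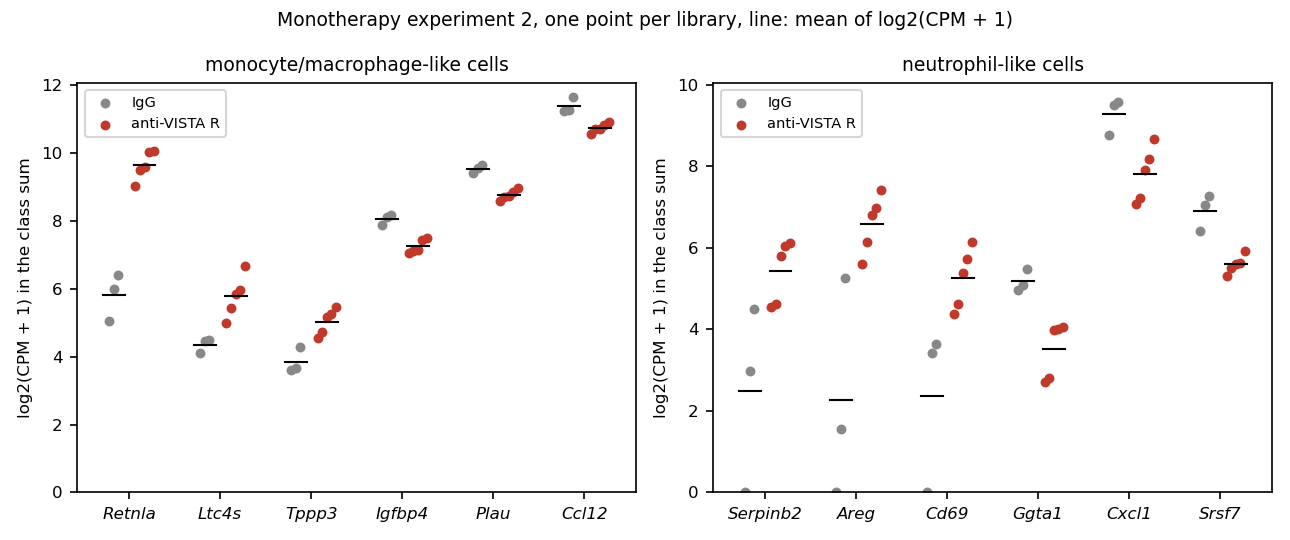
The named genes of monotherapy experiment 2 per library, as log2 of CPM plus 1 (y axis) in the summed monocyte/macrophage-like cells (left) and neutrophil-like cells (right), with a line at each mean. Grey points are the 3 IgG libraries and red points the 5 anti-VISTA R libraries; for every gene shown the R libraries lie on 1 side of the IgG mean.

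Neutrophil-like cells of the same R tumours had higher granule and lower dissociation stress lists than those under IgG. Within the immature neutrophil granule list, Mmp8 (ENSMUSG00000005800), the neutrophil collagenase, rose by 1.44 ± 0.23, Lcn2 (ENSMUSG00000026822) by 1.41 ± 0.16, Padi4 (ENSMUSG00000025330) by 1.29 ± 0.31, and Anxa1 (ENSMUSG00000024659) by 0.92 ± 0.14. These were the 4 of 8 tested members that passed (7 when adjusted within the list; median 1.43, camera adjusted p = 4.08e-12; adjusted p = 0.142 at estimated correlation). Serpinb2 (ENSMUSG00000062345) rose by 2.83 ± 0.63, Areg (ENSMUSG00000029378) by 2.54 ± 0.55, and Cd69 (ENSMUSG00000030156) by 2.26 ± 0.52, with edgeR adjusted p from 0.0186 to 0.0243. Cxcl1 (ENSMUSG00000029380), a neutrophil-attracting chemokine, went from 639 ± 177 (SD, n = 3) to 243 ± 111 CPM (SD, n = 5), a change of -1.39 ± 0.28 (edgeR adjusted p = 0.0119). Ggta1 (ENSMUSG00000035778) changed by -1.42 ± 0.35 and Srsf7 (ENSMUSG00000024097) by -1.29 ± 0.22. Of 21 dissociation stress genes, 3 fell (8 when adjusted within the list; median -0.37, adjusted p = 3.25e-08; adjusted p = 0.290 at estimated correlation), namely Atf3 (ENSMUSG00000026628, -0.99 ± 0.15), Ier3 (ENSMUSG00000003541, -0.73 ± 0.14) and Klf6 (ENSMUSG00000000078, -0.69 ± 0.12). In the myeloid suppression list Wfdc17 (ENSMUSG00000069792, 1.73 ± 0.22), S100a8 (ENSMUSG00000056054, 0.68 ± 0.12) and S100a9 (ENSMUSG00000056071, 0.49 ± 0.11) rose, while the list was not called (median 0.07, adjusted p = 0.0674). Each gene named here lay on its side of the other group's mean in all 8 libraries. Of 3579 genes tested, 60 rose and 43 fell, a count of 166 with no filter on low counts, 55 with the stricter cell filter, 27 without IgG replicate 1, 58 without IgG replicate 3 and 164 without R replicate 3. Haemoglobin and other erythroid markers, the trace of lysed red cells, had a median of 8.59 over 5 genes in these sums, with no gene past the threshold.

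No gene passed in CD8 T-like or Treg-like cells under anti-VISTA alone. In CD8 T-like cells edgeR called 0 of 9168 genes, with 657 at an unadjusted p under 0.05, and DESeq2 called 22. The smallest p values belonged to Dapl1 (ENSMUSG00000026989, -1.98 ± 0.34) and Cd7 (ENSMUSG00000025163, 1.52 ± 0.27), both at an adjusted p of 0.293. Of 35 proliferation genes in CD8 T-like cells, 34 lay lower (median -0.29, camera adjusted p = 1.79e-13; adjusted p = 0.601 at estimated correlation), none of them past the threshold over all genes or adjusted within the list. The T cell quiescence list had a median of 0.11 with 18 of 27 positive (adjusted p = 0.0490; adjusted p = 0.822 at estimated correlation). The lists of cytotoxic effector (-0.09, adjusted p = 0.448), T cell exhaustion (0.01, adjusted p = 0.722) and TCR activation genes (-0.00, adjusted p = 0.267) were not called, the means of the last pair having the opposite sign (-0.01 and 0.06). In Treg-like cells edgeR called 0 of 3853 genes (344 at an unadjusted p under 0.05) and DESeq2 1. With no filter on low counts the Treg-like count was 53 and the CD8 T-like count 9, and with the replicate block they were 11 and 4. Without IgG replicate 1 the Treg-like count was 22, without R replicate 1 it was 1, and the CD8 T-like count was 2 and 1 without IgG replicate 3 or R replicate 2. Genes of the Treg programme had a median of -0.25 in Treg-like cells, with 7 of 23 lower when adjusted within the list and none over all genes (camera adjusted p = 6.23e-08; adjusted p = 0.163 at estimated correlation). Plac8 (ENSMUSG00000029322, 3.62 ± 0.66, adjusted p = 0.0586) and Raly (ENSMUSG00000027593, 1.15 ± 0.22, adjusted p = 0.0634) had the smallest p values there.

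Vsir itself was detected in all 4 main classes, and no difference between R and IgG passed. In monocyte/macrophage-like cells it stood at 148 ± 4.52 CPM (SD, n = 5) against 132 ± 13.9 CPM (SD, n = 3), a log2 change of 0.17 ± 0.07 (edgeR adjusted p = 0.163). The changes in CD8 T-like, Treg-like and neutrophil-like cells were -0.06 ± 0.11, -0.12 ± 0.26 and 0.22 ± 0.18. Of its partner and fellow checkpoint genes, Selplg (ENSMUSG00000048163), which encodes a VISTA-binding adhesion ligand, Pdcd1 (ENSMUSG00000026285), Ctla4 (ENSMUSG00000026011) and Cd274 (ENSMUSG00000016496), which encodes PD-L1, none passed in any class of this comparison. No cell class share passed: CD8 T-like cells made up 7.88 ± 1.96% (SD, n = 5) of R against 5.66 ± 1.84% (SD, n = 3) of IgG cells (two-sided exact permutation p = 0.143), and monocyte/macrophage-like cells 53.4 ± 4.78% against 57.5 ± 1.78% (exact p = 0.214). The lowest adjusted p over 13 classes was 0.542, and 56 groupings allow no p below 0.0179.

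Monotherapy experiment 1, with 1 library per group and no test, gave values only. In its monocyte/macrophage-like cells Retnla was higher than under IgG in R (149 CPM, log2 ratio 2.86) and in NR (88.0 CPM, log2 ratio 2.16). MHC class II genes had a median log2 ratio of 1.06 in R and 0.78 in NR, interferon-gamma response genes 0.89 and 0.61, and type I interferon genes 0.50 (20 of 21 positive) and 0.35 (19 of 20), each above all 10000 random lists matched on expression. The sign of the type I interferon list was thus opposite to its median of -0.12 in experiment 2. Proliferation genes had a median of -0.39 in R and -0.21 in NR. Lyve1 (ENSMUSG00000030787) had the lowest ratio in R (-1.99) and NR (-1.85). Of the 479 genes called in experiment 2, 248 had the same sign in the R library of experiment 1 (122 of the 328 that rose and 126 of the 151 that fell), and 238 had it in NR; 37.3% and 40.0% of all measured genes were higher than under IgG there. Among the experiment 2 genes, Ltc4s had the opposite sign in R (-0.93) and NR (-1.11), while Igfbp4, Plau and Ccl12 were lower in both. In CD8 T-like cells Csf2 (ENSMUSG00000018916), the cytokine GM-CSF, was lower in R (11.6 against 162 CPM, log2 ratio -3.00) and also lower in NR (33.0 CPM), cytotoxic effector genes had medians of 0.68 and 0.40, and quiescence genes 0.62 and 0.42. Macrophage markers in these CD8 T-like sums had medians of 0.77 over 5 genes and 0.33 over 3 (the latter -0.10 with genes of at least 10 CPM), NK markers 0.61 and 0.48 over 3 genes (percentiles 98.8 and 98.7), and dissociation stress genes 0.38 and 0.10 (percentiles 99.7 and 88.4).

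In the combination arm, CP alone was set against no treatment in experiment 1, with the CP libraries of both experiments sharing the model's experiment term. In macrophage-like cells Ltc4s rose from 12.2 ± 7.33 (SD, n = 3) to 110 ± 39.9 CPM (SD, n = 7), a log2 change of 2.97 ± 0.43 (edgeR adjusted p = 0.000839). Cd36 (ENSMUSG00000002944), a scavenger receptor for lipids, rose by 1.83 ± 0.26 (adjusted p = 0.000814), and Timd4 (ENSMUSG00000055546) by 1.85 ± 0.44. Mgl2 (ENSMUSG00000040950) changed by -2.39 ± 0.36 (adjusted p = 0.00106), Cxcl13 (ENSMUSG00000023078) by -2.06 ± 0.50, and Vcam1 (ENSMUSG00000027962) by -1.49 ± 0.27. Of 27 myeloid suppression genes, Wfdc17 (1.67 ± 0.27) and Arg1 (ENSMUSG00000019987), which encodes arginase 1 (1.14 ± 0.22), rose, also when adjusted within the list (median 0.15, camera adjusted p = 0.0311; adjusted p = 0.851 at estimated correlation). The inflammatory monocyte list had 12 of 13 genes positive (median 0.46, adjusted p = 0.000267; adjusted p = 0.622 at estimated correlation), with Fn1 (ENSMUSG00000026193), fibronectin, at 1.32 ± 0.29 as the 1 gene past the threshold and 2 adjusted within the list. The hypoxia and glycolysis list had 24 of 26 positive (median 0.31, adjusted p = 7.45e-07; adjusted p = 0.828 at estimated correlation), with Ankrd37 (ENSMUSG00000050914) rising by 1.11 ± 0.21, alone also when adjusted within the list. Of the complement and scavenger list, Apoe (ENSMUSG00000002985, -1.11 ± 0.28) and Axl (ENSMUSG00000002602, -0.71 ± 0.16) fell and Folr2 (ENSMUSG00000032725) rose (0.94 ± 0.20). Every gene named here lay on its side of the other group's mean in all 10 libraries. Of 12070 genes, 192 rose and 126 fell. The count was 154, 493 and 137 without untreated replicate 1, 2 or 3, 115 in experiment 1 alone, 513 with DESeq2, 191 with the replicate block, 159 with thinned libraries and 69 with only these groups in the fit. Tumour and stromal markers in these macrophage-like sums had a median of -1.24, with 8 of 13 genes lower (adjusted p = 0.0210 at estimated correlation).

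No gene passed between CP and untreated in CD8 T-like cells: edgeR called 0 of 9517, with 437 at an unadjusted p under 0.05, and DESeq2 called 10. The edgeR count was 211 with no filter on low counts, 2 without untreated replicate 1, 2 without untreated replicate 3 and 8 without experiment 1 CP replicate 2. Ccl2 (-3.52 ± 0.65) and Clec4n (ENSMUSG00000023349, -3.34 ± 0.66), both myeloid genes, had the smallest p values (adjusted p = 0.0916), and macrophage markers in the same CD8 T-like sums had a median of -1.64 over 26 genes (adjusted p = 0.0756 at estimated correlation). Cytotoxic effector genes were higher as a set, 19 of 25 positive with a median of 0.46 (camera adjusted p = 1.37e-06; adjusted p = 0.241 at estimated correlation), and 1 member passed when adjusted within the list. In neutrophil-like cells 5 genes rose and none fell among 2709 (36 changed with DESeq2, 64 with no filter on low counts, 30 with the replicate block and 240 with only these groups in the fit), 4 CP libraries of experiment 2 being set against 2 untreated libraries of experiment 1 through the other groups of the model. They included the interferon-inducible GTPases Gbp9 (ENSMUSG00000029298, 3.38 ± 0.54), Irgm1 (ENSMUSG00000046879, 2.21 ± 0.42) and Ifi47 (ENSMUSG00000078920, 2.10 ± 0.35), and Cd274 (1.72 ± 0.32). Their edgeR adjusted p ran from 0.0110 to 0.0281. The interferon-gamma response list had 22 of 24 genes positive and 15 higher when adjusted within the list (median 1.40, adjusted p = 1.47e-12; adjusted p = 0.622 at estimated correlation). The type I list had all 24 positive, none past the threshold and 10 adjusted within the list (median 0.91, adjusted p = 1.00e-11; adjusted p = 0.622 at estimated correlation). The neutrophil-like count was 41 without untreated replicate 3, 3 without experiment 2 CP replicate 2 and 8 without experiment 2 CP replicate 3. Treg-like cells could not be tested, since no untreated library held 20 of them. No class share differed in experiment 1 (12 classes; 3 against 3 libraries allow no exact permutation p below 0.1).

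**Figure D2:**
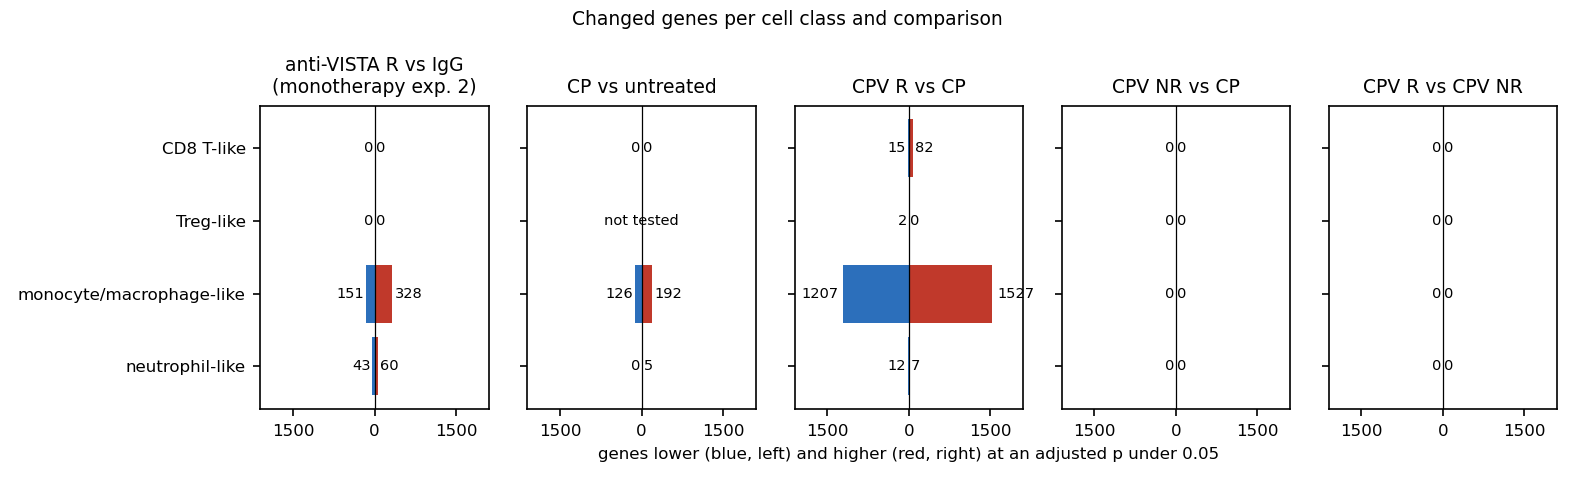
Number of genes lower (blue, left) and higher (red, right) at an edgeR adjusted p under 0.05 in each main cell class (y axis), with 1 panel per comparison and the count beside each bar. Monocyte/macrophage-like cells of CPV R against CP gave 1207 lower and 1527 higher genes.

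Adding anti-VISTA to CP, in tumours that responded, went with an interferon programme in macrophages. In monocyte/macrophage-like cells all 27 tested type I interferon response genes rose in CPV R against CP (27 when adjusted within the list), with a median log2 change of 1.03. They included the antiviral effectors Ifit3b (ENSMUSG00000062488, 2.26 ± 0.45), Isg20 (ENSMUSG00000039236, 1.90 ± 0.36), Cmpk2 (ENSMUSG00000020638, 1.84 ± 0.38) and Rsad2 (ENSMUSG00000020641, 1.83 ± 0.40). Of 31 interferon-gamma response genes 25 rose (29 adjusted within the list; median 0.72), among them Ido1 (ENSMUSG00000031551), a tryptophan-degrading enzyme (1.53 ± 0.38), Socs1 (ENSMUSG00000038037), a brake on cytokine signalling (1.42 ± 0.26), and the GTPase genes Irgm1 (1.04 ± 0.23) and Gbp2 (ENSMUSG00000028270, 0.98 ± 0.27). Of 15 MHC class II presentation genes 10 rose, 10 also adjusted within the list (median 0.70), including the class II chains H2-Aa (ENSMUSG00000036594, 1.00 ± 0.24) and H2-Eb1 (0.95 ± 0.25), H2-Oa (ENSMUSG00000024334, 1.27 ± 0.40) and the co-stimulatory receptor Cd40 (ENSMUSG00000017652, 0.94 ± 0.23). Camera gave adjusted p = 3.79e-20, 1.15e-15 and 2.84e-06 for these 3 lists, which became adjusted p = 0.191, 0.191 and 0.220 at estimated correlation. Cd274 rose from 202 ± 119 (SD, n = 7) to 376 ± 105 CPM (SD, n = 5), a change of 0.90 ± 0.28 (edgeR adjusted p = 0.0276), with all 5 R libraries above the CP mean. Vsir did not differ (0.03 ± 0.07, adjusted p = 0.820).

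The same macrophage-like cells carried fewer cell-cycle transcripts. Of 35 proliferation genes 32 fell (33 adjusted within the list; median -0.81, camera adjusted p = 3.56e-17; adjusted p = 0.205 at estimated correlation), with the mitotic kinase gene Plk1 (ENSMUSG00000030867) at -1.19 ± 0.28 and Ccnb1 at -1.17 ± 0.31. Of 13 inflammatory monocyte genes 6 rose and 1 fell (9 and 2 adjusted within the list; median 0.59, adjusted p = 0.00308; adjusted p = 0.316 at estimated correlation). Ly6c2 (ENSMUSG00000022584), a surface antigen of classical monocytes, rose by 1.67 ± 0.36, and Sell (ENSMUSG00000026581), which encodes L-selectin, by 1.44 ± 0.29. Of 19 complement and scavenger macrophage genes 7 fell and 2 rose (8 and 2 adjusted within the list; median -0.25, adjusted p = 0.0432; adjusted p = 0.471 at estimated correlation). Gas6 (ENSMUSG00000031451), a bridge to apoptotic cells, changed by -1.39 ± 0.29, Mrc1 (ENSMUSG00000026712), the mannose receptor, by -1.01 ± 0.25 and Folr2 by -0.99 ± 0.16. Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, rose from 10.3 ± 7.20 (SD, n = 7) to 77.7 ± 94.3 CPM (SD, n = 5), by 2.85 ± 0.56 (edgeR adjusted p = 0.00290). Ifit1bl1 (ENSMUSG00000079339), an interferon-induced gene, rose by 2.14 ± 0.43. Alox5 (ENSMUSG00000025701), the lipoxygenase that starts leukotriene synthesis, changed by -2.21 ± 0.35 and Ltc4s by -1.72 ± 0.32 (adjusted p = 0.00167 and 0.00221). Cbr2 (ENSMUSG00000025150) went from 408 ± 197 to 84.2 ± 33.3 CPM (-2.29 ± 0.38, adjusted p = 0.00167).

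Genes of suppression and inflammation moved in both directions in these cells. Of 27 myeloid suppression genes 10 rose and 4 fell (11 and 5 adjusted within the list), and the list was not called (median 0.22, camera adjusted p = 0.119): Ido1, Il10 (ENSMUSG00000016529), an anti-inflammatory cytokine (1.21 ± 0.34), and Ptges (ENSMUSG00000050737), a prostaglandin synthase (1.22 ± 0.42), rose while Wfdc17 changed by -1.11 ± 0.20. Of 21 inflammatory cytokine genes 5 rose and 1 fell, over all genes and adjusted within the list (median 0.38, adjusted p = 0.00447; adjusted p = 0.576 at estimated correlation), including Il1b (ENSMUSG00000027398, 0.71 ± 0.23), Nlrp3 (ENSMUSG00000032691), an inflammasome sensor (0.81 ± 0.21), and Ptgs2 (ENSMUSG00000032487, 0.83 ± 0.29). Of 24 dissociation stress genes 6 rose (8 adjusted within the list; median 0.38, adjusted p = 7.72e-05; adjusted p = 0.333 at estimated correlation), among them Btg2 (ENSMUSG00000020423, 0.74 ± 0.16) and the heat shock gene Hsph1 (ENSMUSG00000029657, 0.70 ± 0.15). Vegfa (ENSMUSG00000023951), an angiogenic factor, rose by 0.86 ± 0.17, and the hypoxia and glycolysis list was not called (median 0.13, adjusted p = 0.265). Oxidative phosphorylation genes had a median of -0.07 (adjusted p = 0.0484; adjusted p = 0.751 at estimated correlation). Neutrophil markers in these sums had a median of 0.73, with 5 of 21 higher and 1 lower. Of 12070 genes in macrophage-like cells, 1527 rose and 1207 fell. Without experiment 2 CPV R replicate 3 the total of 2734 became 1627. Experiment 1 alone (2 against 3) gave 0 and experiment 2 alone 1942. Signs matched in 2716 of the 2734 genes, which both experiments helped to call.

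**Figure D3:**
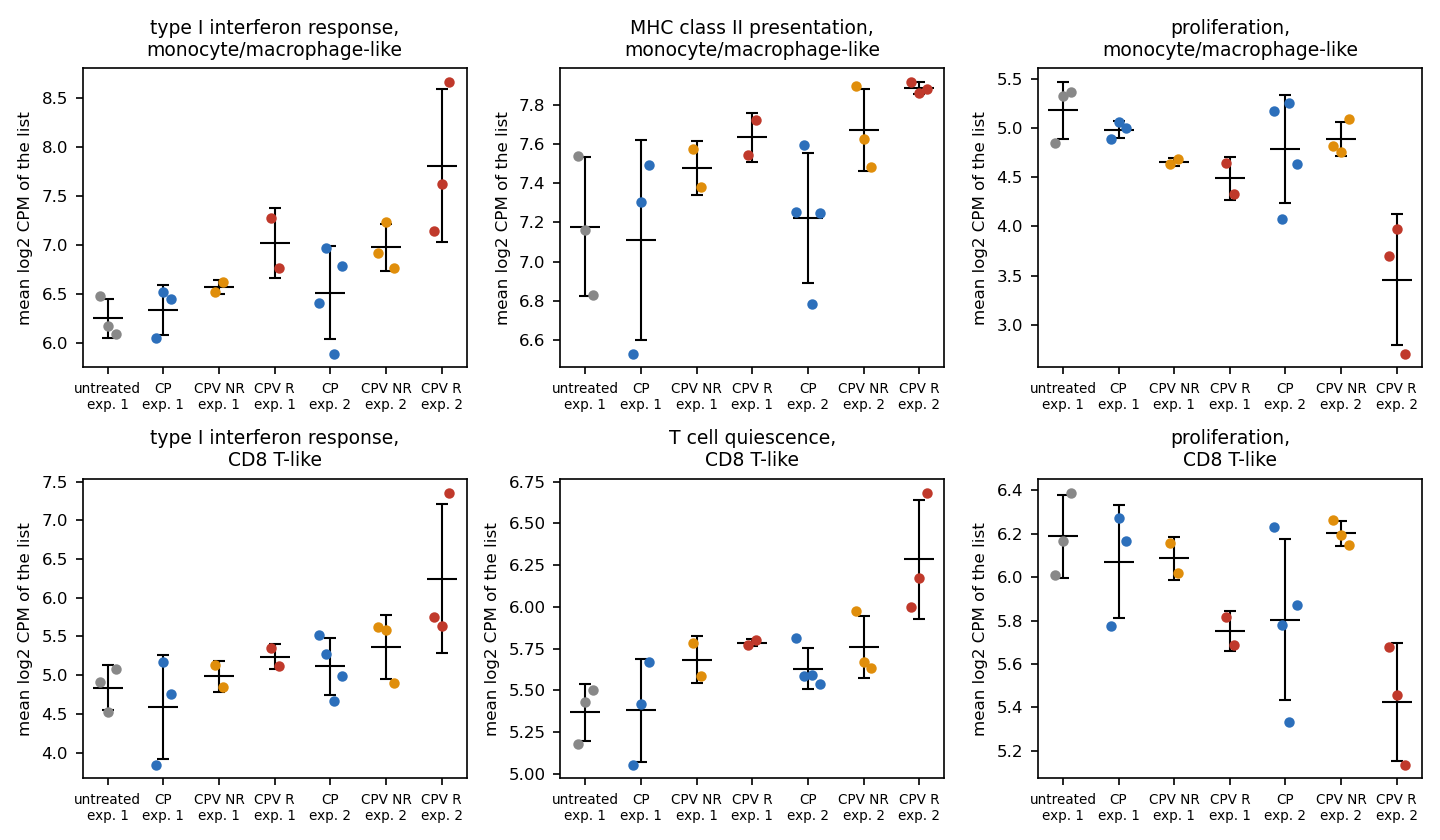
Mean log2 CPM of 4 gene lists, 3 of them per class (y axis), in summed monocyte/macrophage-like (top) and CD8 T-like cells (bottom) of each combination library, grouped by treatment and experiment, with the mean and SD of each group; each point is a library. In monocyte/macrophage-like cells of experiment 2 the CPV R libraries reached 8.67 for type I interferon response genes and fell to 2.70 for proliferation genes, both in replicate 3.

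CD8 T-like cells of CPV R tumours had higher interferon and quiescence lists and a lower proliferation list than under CP. Gzma (ENSMUSG00000023132), the protease granzyme A, rose from 39.1 ± 17.6 (SD, n = 7) to 240 ± 265 CPM (SD, n = 5), a change of 2.34 ± 0.42 (edgeR adjusted p = 0.0141). Cxcl10 (ENSMUSG00000034855), a T cell-attracting chemokine, rose by 2.30 ± 0.53 and Ifit1 (ENSMUSG00000034459) by 1.66 ± 0.31. Fdft1 (ENSMUSG00000021273), squalene synthase, changed by -0.76 ± 0.18, Rfc5 (ENSMUSG00000029363) by -0.70 ± 0.15 and Fam64a (ENSMUSG00000020808), a mitotic regulator, by -1.13 ± 0.28 (adjusted p = 0.0499). In the T cell quiescence list 26 of 29 genes were positive and 3 rose (11 adjusted within the list): Il7r (ENSMUSG00000003882), the interleukin-7 receptor (0.85 ± 0.21), Satb1 (ENSMUSG00000023927), a chromatin organiser (0.71 ± 0.17), and Foxo1 (ENSMUSG00000044167), a transcription factor of naive and memory T cells (0.64 ± 0.15). Its median was 0.43 (camera adjusted p = 2.34e-12; adjusted p = 0.0688 at estimated correlation). All 24 type I interferon genes were positive, with 2 past the threshold and 20 adjusted within the list (median 0.81, adjusted p = 2.87e-19; adjusted p = 0.178 at estimated correlation). Of 29 interferon-gamma response genes 4 rose (12 adjusted within the list; median 0.38, adjusted p = 3.64e-11; adjusted p = 0.191 at estimated correlation), Stat1 (ENSMUSG00000026104) among them (0.67 ± 0.13). All 35 proliferation genes were lower, none past either threshold (median -0.40, adjusted p = 1.42e-13; adjusted p = 0.178 at estimated correlation).

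Exhaustion genes (median 0.06, mean -0.01, camera adjusted p = 0.883) and the cytotoxic effector list (0.13, adjusted p = 0.164) were not called in these CD8 T-like cells, and TCR activation genes had a median of 0.25 (adjusted p = 0.0223; adjusted p = 0.191 at estimated correlation) with Tnfaip3 (ENSMUSG00000019850) at 0.59 ± 0.12. Ctla4 (0.46 ± 0.12, edgeR adjusted p = 0.0597), Cd274 (0.70 ± 0.19, adjusted p = 0.0775), Vsir (0.18 ± 0.12, adjusted p = 0.566) and Pdcd1 (0.07 ± 0.11, adjusted p = 0.847) did not pass. Macrophage markers in the same sums had a median of 0.83 over 26 genes and neutrophil markers 1.49 over 10. Of 9517 genes 82 rose and 15 fell in CD8 T-like cells, 97 in all. The 97 became 23 and 50 without experiment 1 CP replicate 1 or 3, and 42 without experiment 1 CPV R replicate 2. They became 37 and 0 without experiment 2 CPV R replicate 1 or 3, and 46, 41, 24 and 15 without experiment 2 CP replicate 1, 2, 3 or 4. Experiment 1 alone gave 0 and experiment 2 alone 142, DESeq2 191, no filter on low counts 510, the stricter cell filter 60, only these groups in the fit 41 and the replicate block 15.

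Treg-like and neutrophil-like cells also gave called genes between CPV R and CP. In Treg-like cells Ccl5 (ENSMUSG00000035042), a T cell chemokine, went from 2710 ± 853 (SD, n = 4) to 669.8 ± 151 CPM (SD, n = 4), a change of -1.93 ± 0.31 (edgeR adjusted p = 0.00759), and Nkg7 (ENSMUSG00000004612), a cytotoxic granule protein, changed by -1.19 ± 0.22 (adjusted p = 0.0311), all 4 libraries of each group on their side. These were the 2 calls among 2637 genes, in sums of 21 to 35 cells. They were 2 of 14 cytotoxic effector genes (4 adjusted within the list; median -0.48, camera adjusted p = 2.99e-08; adjusted p = 0.0241 at estimated correlation). The Treg-like count was 0 without experiment 2 CPV R replicate 1, 4 without experiment 2 CP replicate 4, and 1 without experiment 1 CPV R replicate 1 or CP replicate 1. In neutrophil-like cells Socs1 rose from 233 ± 61.2 (SD, n = 4) to 659 ± 220 CPM (SD, n = 5), by 1.53 ± 0.32 (adjusted p = 0.0409). Cxcl9 (ENSMUSG00000029417), an interferon-gamma-induced chemokine, rose by 2.62 ± 0.59 and Gbp2b (ENSMUSG00000040264) by 1.18 ± 0.25. Stfa3 (ENSMUSG00000054905) changed by -4.14 ± 0.80, Impa2 (ENSMUSG00000024525) by -1.92 ± 0.43 and Pgk1-rs7 (ENSMUSG00000066632), a copy of a glycolysis gene, by -1.71 ± 0.34. Glycolysis enzymes fell with it: 4 of 24 hypoxia and glycolysis genes passed (16 adjusted within the list), all 24 were lower, and the median was -0.78 (adjusted p = 3.79e-20; adjusted p = 0.0593 at estimated correlation). They included Eno1 (ENSMUSG00000063524, -1.29 ± 0.21) and Pgk1 (ENSMUSG00000062070, -1.19 ± 0.23). Interferon-gamma response genes had a median of 0.69, 3 of 24 passing and 16 adjusted within the list (adjusted p = 1.17e-16; adjusted p = 0.178 at estimated correlation). Neutrophil-like cells gave 7 higher and 12 lower of 2709 genes. That total of 19 was 56 with DESeq2, 86 with no filter on low counts, 3 with the stricter cell filter and with thinned libraries, 0 with only these groups in the fit, 9 and 2 without experiment 1 CPV R replicate 1 or 2, 37, 3 and 3 without experiment 2 CPV R replicate 1, 2 or 3, and 8, 72, 3 and 5 without experiment 2 CP replicate 1, 2, 3 or 4. All 4 CP libraries of that test came from experiment 2.

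Cell class shares differed between CPV R and CP in 3 of 14 classes. Type 2 conventional dendritic cells (cDC2-like) made up 2.09 ± 0.283% (SD, n = 5) of CPV R against 1.24 ± 0.232% (SD, n = 7) of CP cells, and plasmacytoid dendritic cells (pDC-like) 1.02 ± 0.249% against 0.569 ± 0.249%. Tumour/stromal-like cells made up 0.497 ± 0.541% against 4.91 ± 8.14%, a CP mean raised by experiment 1 CP replicate 1 (23.2%, the other 6 at 0.694 to 3.55%). For each, the two-sided exact permutation p within experiments was 0.00286, the smallest that 350 groupings allow, and the adjusted p was 0.0133. Within experiments 1 and 2 the cDC2-like share was 2.23% against 1.46% and 2.0% against 1.07%, the pDC-like share 1.20% against 0.765% and 0.902% against 0.422%, and the tumour/stromal-like share 1.03% against 9.95% (3.10% and 3.55% in CP replicates 3 and 2) and 0.140% against 1.12%. The tumour/stromal-like difference passed without experiment 1 CP replicate 1 (adjusted exact p = 0.0222) but not with doublets kept (exact p = 0.277), and the pDC-like difference did not pass with the stricter cell filter (adjusted exact p = 0.156). Experiment 1 alone allows no exact p below 0.1 and experiment 2 alone none below 0.0286, too few groupings for 3 of 14 classes to pass after adjustment (lowest adjusted exact p 0.350 and 0.133). CD8 T-like (9.25 ± 2.14% against 9.40 ± 3.23%, exact p = 0.920) and monocyte/macrophage-like shares (56.8 ± 6.05% against 60.3 ± 8.28%, exact p = 0.289) did not pass. Neither did neutrophil-like ones (9.69 ± 7.10% against 6.08 ± 6.90%, exact p = 0.0257, adjusted p = 0.0900), at 2.46% against 0.350% and 14.5% against 10.4% by experiment. No class passed without experiment 1 CPV R replicate 1 or 2.

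**Figure D4:**
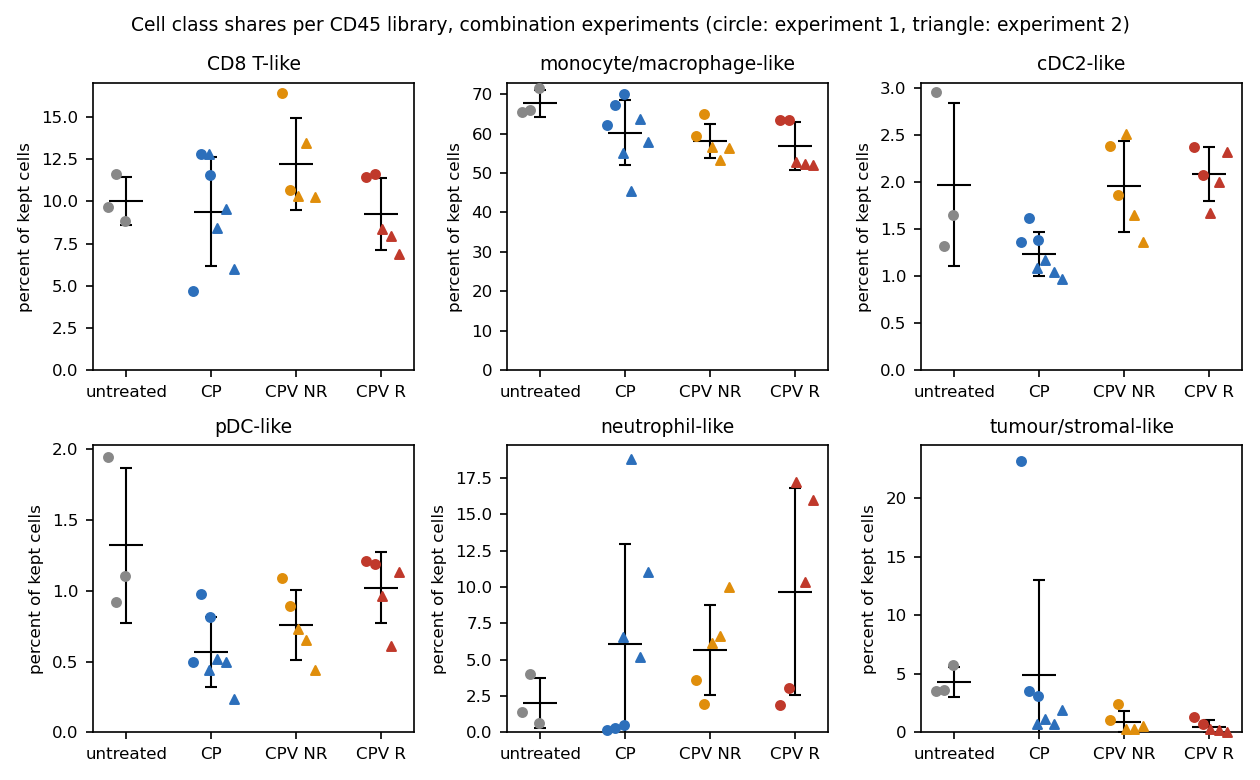
Share of kept cells (y axis, percent) in 6 cell classes for each CD45 library of the combination experiments, by treatment group, with the mean and SD; circles are experiment 1 and triangles experiment 2. In the cDC2-like panel the CPV R libraries average 2.09% and the CP libraries 1.24%.

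In tumours that did not respond to CPV, no gene passed against CP in any main class. For CD8 T-like cells edgeR called 0 of 9517 genes (453 at an unadjusted p under 0.05; DESeq2 7), for Treg-like cells 0 of 2637 (164; DESeq2 2), for monocyte/macrophage-like cells 0 of 12070 (1304; DESeq2 101) and for neutrophil-like cells 0 of 2709 (156; DESeq2 0). All 27 type I interferon genes were positive in monocyte/macrophage-like cells, with a median of 0.32 and none past the threshold over all genes or adjusted within the list (camera adjusted p = 3.88e-05; adjusted p = 0.911 at estimated correlation). MHC class II genes had a median of 0.37 (adjusted p = 0.000271; adjusted p = 0.653 at estimated correlation) and complement and scavenger genes -0.19 (adjusted p = 0.00568; adjusted p = 0.653 at estimated correlation). The cytotoxic effector genes of Treg-like cells had a median of -0.65, with 5 of 14 lower when adjusted within the list (adjusted p = 1.04e-07; adjusted p = 0.0259 at estimated correlation). The smallest p values were those of Psme2b (ENSMUSG00000078153, 0.61 ± 0.13, edgeR adjusted p = 0.161) and Plxnd1 (ENSMUSG00000030123, -1.09 ± 0.25, adjusted p = 0.261) in CD8 T-like cells, and of Nkg7 (-0.99 ± 0.20, adjusted p = 0.0740) and Cd274 (1.73 ± 0.40, adjusted p = 0.196) in Treg-like cells. In monocyte/macrophage-like cells they were those of Jam2 (ENSMUSG00000053062, -1.93 ± 0.36) and Tysnd1 (ENSMUSG00000020087, -0.52 ± 0.10), both at 0.0796. In neutrophil-like cells they were those of Snx20 (ENSMUSG00000031662, -1.61 ± 0.40) and Eno1b (ENSMUSG00000059040, -1.10 ± 0.28), both at 0.597. The immature neutrophil granule list had a median of -1.67 with 9 of 10 lower, 2 adjusted within the list (camera adjusted p = 0.000688; adjusted p = 0.698 at estimated correlation). The cDC2-like share was higher than in CP, 1.96 ± 0.487% (SD, n = 5) against 1.24 ± 0.232% (SD, n = 7; exact permutation p = 0.00286, adjusted p = 0.0400), at 2.12% against 1.46% in experiment 1 and 1.85% against 1.07% in experiment 2. Such classes numbered 2 without experiment 1 CP replicate 1, 2 or 3 and 0 without any other single library. There the groupings allow no single class to pass, the cDC2-like logit difference being 0.36 to 0.52 (0.46 with all). With no filter on low counts edgeR called 116, 21, 38 and 28 in the opening class order. Single libraries left out gave at most 12 in monocyte/macrophage-like (experiment 2 CP replicate 2), 3 in CD8 T-like (experiment 2 CPV NR replicate 2) and 2 in Treg-like cells (experiment 2 CP replicate 4).

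The direct comparison of responding with non-responding CPV tumours gave no single gene past the edgeR threshold in the main classes. The edgeR count was 0 in CD8 T-like (894 genes at an unadjusted p under 0.05; DESeq2 10), Treg-like (124; DESeq2 0), monocyte/macrophage-like (2442; DESeq2 378) and neutrophil-like cells (290; DESeq2 18). With no filter on low counts it was 242, 13, 83 and 62 in the same order. Without experiment 1 CPV R replicate 1 it was 141 in monocyte/macrophage-like cells, and without experiment 1 CPV NR replicate 1 it was 4 in neutrophil-like cells. As sets, interferon genes were higher and proliferation genes lower in responders. In monocyte/macrophage-like cells all 27 type I interferon genes were higher adjusted within the list (median 0.75, camera adjusted p = 1.64e-17; adjusted p = 0.273 at estimated correlation) and 32 of 35 proliferation genes lower (median -0.72, adjusted p = 4.27e-24; adjusted p = 0.207 at estimated correlation). In CD8 T-like cells 24 of 35 proliferation genes were lower adjusted within the list (median -0.56, adjusted p = 3.68e-29; adjusted p = 0.134 at estimated correlation). Quiescence genes had a median of 0.41 there, 7 of 29 adjusted within the list (adjusted p = 8.76e-09; adjusted p = 0.135 at estimated correlation), and cytotoxic effector genes 0.29, 3 of 25 (adjusted p = 0.000163; adjusted p = 0.199 at estimated correlation). In neutrophil-like cells 16 of 24 hypoxia and glycolysis genes were lower adjusted within the list (median -0.62, adjusted p = 4.88e-17; adjusted p = 0.134 at estimated correlation) and 16 of 24 interferon-gamma response genes higher (median 0.69, adjusted p = 2.34e-17; adjusted p = 0.179 at estimated correlation). None of these passed over all genes. The smallest p values belonged to Ramp3 (ENSMUSG00000041046, 1.28 ± 0.25, edgeR adjusted p = 0.251) and the neutrophil gene S100a8 (2.93 ± 0.61) in CD8 T-like cells. They belonged to Traf3 (ENSMUSG00000021277), a signalling adaptor (0.57 ± 0.12), and Lrmp (ENSMUSG00000030263, -0.48 ± 0.09), both at 0.116, in monocyte/macrophage-like cells. In neutrophil-like cells they were those of P4hb (ENSMUSG00000025130, -0.87 ± 0.16, adjusted p = 0.0860) and Irf1 (ENSMUSG00000018899), an interferon-induced transcription factor (1.34 ± 0.27, adjusted p = 0.0871). In Treg-like cells they were those of Hsp90aa1 (ENSMUSG00000021270, 0.99 ± 0.23, adjusted p = 0.761) and Odc1 (ENSMUSG00000011179, 0.95 ± 0.25, adjusted p = 0.816). Neutrophil markers in the CD8 T-like sums had a median of 2.29, all 10 higher. CD8 T-like cells made up 9.25 ± 2.14% (SD, n = 5) of responders against 12.2 ± 2.70% (SD, n = 5) of non-responders (exact permutation p = 0.05, adjusted p = 0.389). No class share passed, and 120 groupings allow no p below 0.0167, too high for a single class to pass after adjustment over 14.

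AH1 tetramer-sorted cells, the T cells that recognise a CT26 antigen, were profiled in 1 library per group (2 for monotherapy R), so that their values carry counting error only and no test. In the monotherapy arm some granzyme genes were among the lowest against IgG. All ratios rest on the 1 IgG library, which stood apart in at least 1 respect: the ratio of H2-Q10 (ENSMUSG00000067235), a class I gene, to its near copy H2-Q1 (ENSMUSG00000079507) was 2.35 there and 0.100 to 0.210 in the other 3 libraries, and its excess over the highest of them was 10.7-fold in CD8 T-like and 11.8-fold in monocyte/macrophage-like cells. Gzmf (ENSMUSG00000015441) stood at 1824 CPM under IgG, 414 in NR, and 538 and 675 in R replicates 1 and 2, and Gzmg (ENSMUSG00000040284) at log2 ratios of -1.72, -1.73 and -1.75. In NR Gzmd (ENSMUSG00000059256, -1.84) and Gzme (ENSMUSG00000022156, -1.73) were also among the lowest, and in R Gzmc (ENSMUSG00000079186) was at -2.03 in replicate 2. Among the highest genes in R were Cnih2 (ENSMUSG00000024873, 0.94 and 1.98), Sp140 (ENSMUSG00000070031), a chromatin reader of immune cells (1.09 in replicate 2), and Ass1 (ENSMUSG00000076441), an arginine-synthesis enzyme (0.87 and 0.84, but 0.08 and -0.04 within CD8 T-like clusters in AH1 monotherapy R1 vs IgG and AH1 monotherapy R2 vs IgG). Type I interferon genes had medians of 0.11 and 0.24 in R (99.3 and 100.0 percentile of 10000 random lists) and -0.08 in NR. With genes of at least 10 CPM the type I interferon response median of AH1 monotherapy R1 vs IgG was -0.03, and macrophage markers in the R sums had medians of 0.04 and 0.26, above most or all of the random lists. NK markers (-0.76 and -0.68) and neutrophil markers (-0.17 and -0.69) in those sums lay below nearly all, and NK-like cells made up 12.2% of the IgG library and 8.73% and 6.58% of the R libraries, so that the granzyme values are not of T cells alone. Within CD8 T-like clusters Gzmg was at -0.59 in AH1 monotherapy NR vs IgG, -0.59 in AH1 monotherapy R1 vs IgG and -0.34 in AH1 monotherapy R2 vs IgG, and Gzmf at -1.39, -1.26 and -0.96. Cytotoxic effector genes had a median of -0.31 in NR (percentile 0), exhaustion genes -0.19 (percentile 0.08) and quiescence genes 0.11 (percentile 99.95). In R replicates 1 and 2 the cytotoxic effector medians were -0.03 and 0.16 (percentiles 42.0 and 99.8) and the exhaustion medians 0.03 and 0.18 (percentiles 87.3 and 99.7). The highest genes in NR were stromal or tumour transcripts such as Pcolce (ENSMUSG00000029718), a collagen-processing enhancer (2.83), Tm4sf1 (ENSMUSG00000027800, 2.78), Baiap2l1 (ENSMUSG00000038859, 2.56), Rhox5 (ENSMUSG00000095180, 2.37) and Cav1 (ENSMUSG00000007655, 2.33), and markers of tumour and stroma had a median of 2.25, erythroid markers 4.08 (percentile 100.0), macrophage markers -0.23 (percentile 0) and dissociation stress genes -0.16 (percentile 0.15). T cell clusters held 45.3% to 58.8% of the cells in these 4 libraries, and within CD8 T-like clusters alone the NR medians were 0.15 for cytotoxic effector and 0.19 for exhaustion genes. Vsir was within 0.13 of the IgG level on the log2 scale in all 3.

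In the combination arm, AH1-sorted cells under CP had higher type I interferon and cytotoxic effector lists than untreated ones. The untreated library also differed from the other 3 in holding 0 antibody tag UMIs (309698 or more in each of them), so that handling and treatment cannot be told apart in this comparison. Ly6c1 (ENSMUSG00000079018), a surface antigen of activated and memory CD8 T cells, stood at 655 against 76.1 CPM (log2 ratio 2.95), Ly6c2 at 2.57, Ly6a (ENSMUSG00000075602) at 2.37, Ifit1 at 2.34 and Ccl5 at 2.32. All 13 measured type I interferon genes were higher (median 1.18), cytotoxic effector and quiescence genes had medians of 0.57 and 0.56, each at percentile 100.0, and proliferation genes -0.47 (percentile 0). Dissociation stress genes, which sample handling can raise, moved as well (median 0.32, 18 of 20 positive, percentile 100.0), and so did markers of other cells: NK 0.36 over 4 genes and monocyte/macrophage 0.32 over 6 (percentile 98.7 each; the latter -0.37 with genes of at least 10 CPM), and erythroid -3.49 over 3 (percentile 0). Vsir was higher by 0.87, Ctla4 by 0.73 and Pdcd1 by 0.38. Gzmf (-1.55), Gzmc (-1.42), Ccdc184 (ENSMUSG00000029875, -2.01), Galnt18 (ENSMUSG00000038296, -1.92) and Tmprss6 (ENSMUSG00000016942, -1.69) were lowest. With CPV NR against CP, quiescence (-0.61), TCR activation (-0.52) and type I interferon genes (-0.49) lay below all random lists, and so did dissociation stress genes (-0.50). Exhaustion genes had a median of 0.22 (percentile 99.95) and cytotoxic effector genes -0.12 (percentile 1.56). Markers of mature dendritic cells (-0.69 over 3 genes, percentile 0.605), which include Ccr7, of Treg (-0.32 over 6, below nearly all random lists) and of NK cells (0.28 over 5, percentile 99.0) moved too, and Treg-like cells made up 0.385% against 2.31% of CP. Proliferation genes lay above them (0.26), but had a median of -0.06 within CD8 T-like clusters. Xcl1 (ENSMUSG00000026573), a chemokine for cross-presenting dendritic cells, stood at 83.0 against 538 CPM, Ccr7 (ENSMUSG00000037944), the lymph-node homing receptor, at 127 against 758, and Ccl1 (ENSMUSG00000020702), Emb (ENSMUSG00000021728) and Itgb7 (ENSMUSG00000001281) at -2.33, -2.29 and -1.99. Tff1 (ENSMUSG00000024032, 1.83), Eno3 (ENSMUSG00000060600, 1.13), Filip1 (ENSMUSG00000034898, 0.97) and the chemokine genes Ccl3 (ENSMUSG00000000982, 1.27) and Ccl4 (ENSMUSG00000018930, 0.94) were highest.

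With CPV R against CP, the highest genes of the AH1 sort were myeloid: Ccl2 (752 against 17.9 CPM), Il1b, S100a9, Ccl7 (ENSMUSG00000035373) and Ccl6 (ENSMUSG00000018927), at log2 ratios of 4.77, 4.43, 4.36, 4.30 and 3.94. Monocyte/macrophage-like cells made up 7.50% (exact 95% interval 6.35 to 8.78%) of that library and 0.543% (0.311 to 0.880%) of CP, although the sort excluded cells with macrophage and dendritic surface antigens. Quiescence genes had a median of -0.41 and TCR activation genes of -0.47 (percentile 0 each), with Foxo1 at -1.26, Ccr7 at -1.19, Gramd3 (ENSMUSG00000001700) at -1.61 and Rora (ENSMUSG00000032238) at -1.49. Type I interferon genes had a median of 0.16 over all sorted cells and -0.43 within CD8 T-like clusters, and markers of monocytes and macrophages 2.56 and -0.42. Neutrophil markers had a median of 2.85 over 8 genes (percentile 100.0) and Treg markers -0.42 over 6 (percentile 0.75), and Treg-like cells made up 0.372% against 2.31% of CP. Exhaustion genes had a median of -0.32 (percentile 0.1) and cytotoxic effector genes -0.21 (percentile 0.425).

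Ly6G-sorted myeloid cells under anti-VISTA, 1 library against 1 of IgG, had a higher type I interferon list and a lower proliferation list. Ly6c1 stood at 260.2 against 49.1 CPM (log2 ratio 2.19), Ly6c2 at 2.19, Ly6a at 1.96, Plac8 at 1.93 and Lcn2 at 1.80. Cbr2 (-1.97), Fcrls (ENSMUSG00000015852, -1.76), Gas6 (-1.70), Gzmc (-1.74) and Gzmf (-1.69) were lowest. Of 21 type I interferon genes 20 were higher (median 0.58, percentile 100.0), the granule list had a median of 0.53 over 3 genes, and proliferation genes had a median of -0.68 (percentile 0). Markers of monocytes and macrophages had a median of -0.26 (percentile 0). Myeloid suppression genes had a median of 0.29 and MHC class II genes 0.34 over all cells, but -0.05 and -0.17 within neutrophil-like clusters. Neutrophil-like cells made up 19.4% (exact 95% interval 18 to 20.8%) of the IgG and 28.3% (27.0 to 29.6%) of the anti-VISTA library, and monocyte/macrophage-like cells 62.3% and 50.3%. Vsir had a log2 ratio of -0.17 and Cd274 of 0.54.

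**Figure D5:**
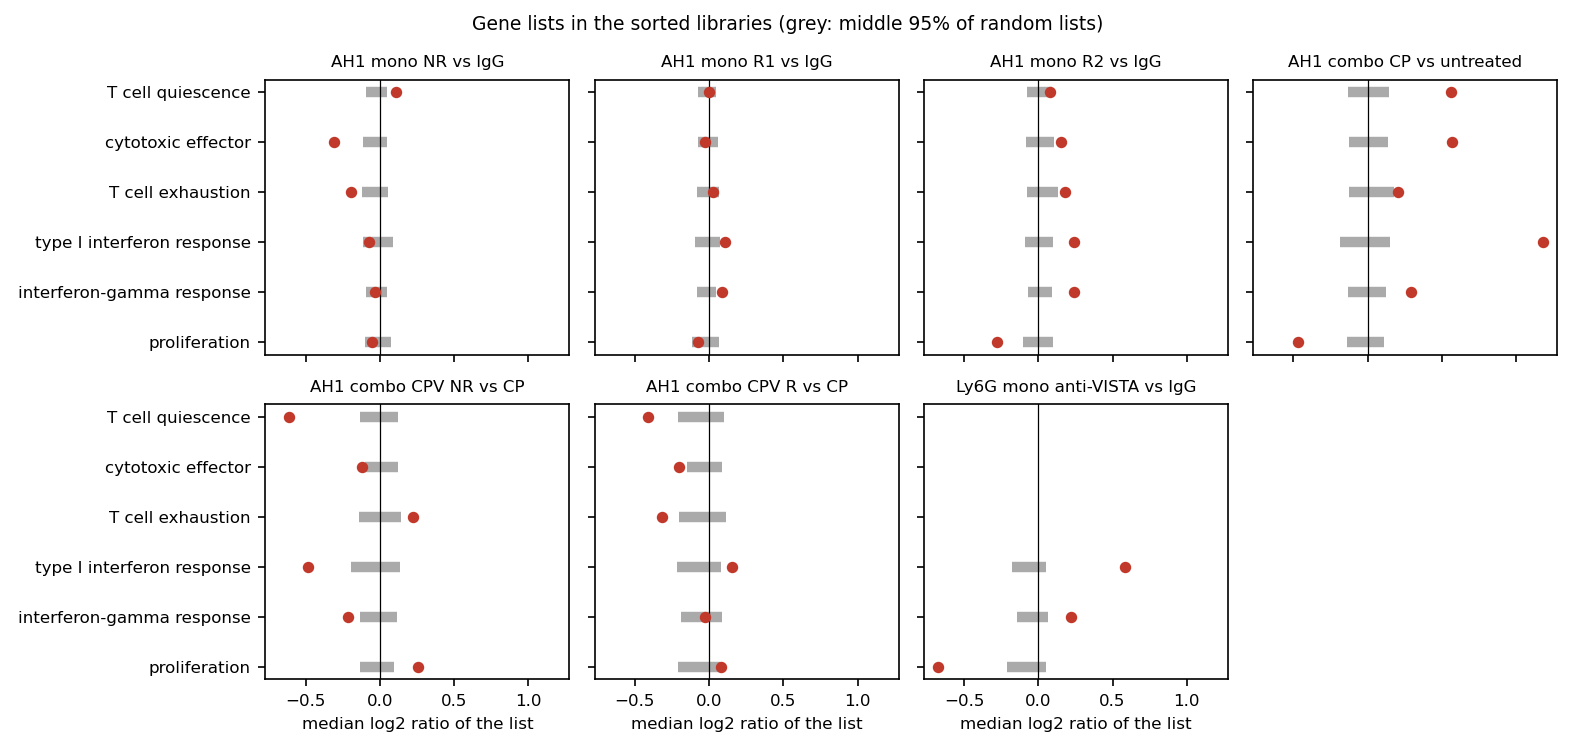
Median log2 ratio (x axis) of 6 gene lists in the sorted libraries (red points), 1 panel per comparison, with the middle 95% of the medians of 10000 random lists matched on expression in grey; the T cell lists were not used for the Ly6G sort. Type I interferon genes stand at 1.18 in CP against untreated AH1 cells and at 0.58 in Ly6G cells under anti-VISTA.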

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

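The depth test of the macrophage interferon rise and the copy test of the experiment-dependent genes were chosen after the result was seen; the interferon-cluster, macrophage RNA, cycling cell and glycolysis tests were written before. A sample far from the rest of its group by Dixon's test at 95% was found in 4 of 66 groups, near the 1 in 20 that chance gives. The share of cDC1-like cells was 2.71% in monotherapy experiment 2 anti-VISTA R replicate 1, with the other 4 at 1.60 to 1.92%. In combination experiment 2, Ifit1 stood at 69.1 CPM in CD8 T-like cells of CP replicate 2, Rfc5 at 54.8 CPM in CD8 T-like cells of CP replicate 4 and Cxcl9 at 4.22 CPM in neutrophil-like cells of CP replicate 3. By an interaction term in edgeR, the CPV R against CP change differed between experiments for 6 genes in CD8 T-like cells. The CPV NR against CP change differed for 22 genes in CD8 T-like, 31 in monocyte/macrophage-like, 8 in NK-like and 3 in cDC2-like cells. Antibody tag UMIs went unused: 3304455 in the pooled Ly6G library, 52869 and 18425 in the Ly6G monotherapy IgG and anti-VISTA libraries, and 797111, 372407 and 309698 in the AH1 combination CP, CPV NR and CPV R libraries, against 0 in the untreated AH1 library, their only untreated control.

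The macrophage interferon rise of CPV R against CP coincides with lower depth of the CPV libraries of experiment 2. Between CPV R and CPV NR the list's median was still 0.75, which is unlikely under depth alone because those groups had median class totals of 9525990 and 8067790 UMIs. The difference in list score behind it fell to 0.43 without experiment 2 CPV R replicate 3 (exact permutation p = 0.05). Leaving out the interferon-led clusters lowered the R against CP median, here from mean log2 CPM differences within experiments rather than the edgeR fit, from 0.92 to 0.39. Those clusters were picked by interferon genes, so that leaving them out had to lower the list, and whether a larger share of such cells gave the rise stays open.

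In CD8 T-like cells, macrophage RNA at its markers' level could give 14.4% of the summed interferon rise, 259 of 1798 CPM. Macrophages are the abundant neighbour here, and the CD45 enrichment does not remove them. Fewer cycling cells are an unlikely source of the quiescence rise, since the median was 0.45 without cells holding 5 or more proliferation genes and 0.48 with them, both from mean log2 CPM differences within experiments. How many cells count as cycling depends on depth.

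Of the 31 macrophage genes whose CPV NR change differed between experiments, 51.6% had names of predicted gene models (Gm and a number) or names ending in -ps or -rs, with or without a number, against 4.06% of those tested (Fisher exact p = 7.32e-15). Pgk1-rs7, for example, changed by 1.15 in experiment 1 and -0.97 in experiment 2, and Rpl27-ps3 by 1.09 and -0.80. Reads shared between near-identical copies are a candidate explanation. A difference in glycolysis is another: the remaining hypoxia and glycolysis genes had a median difference of -0.44 between experiments, which does not separate the explanations.

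Regrouping the libraries tested chance. For anti-VISTA R against IgG, 1 of 56 splits gave as many calls as the real 479 in monocyte/macrophage-like cells (highest other 1). In neutrophil-like cells 1 of 56 gave as many as the real 103 (highest other 5). In each class that 1 was the real grouping. Chance is thus unlikely there, but 56 splits, not adjusted over classes and comparisons, cannot exclude it. A real count of 0 is reached by every split whatever the data, so that the splits test nothing there: in CD8 T-like and Treg-like cells 56 of 56 did so (highest other 2 and 4). For CPV R against CP, 1 of 100 splits reached the real 97 in CD8 T-like (highest other 1) and 1 of 100 the real 2734 in monocyte/macrophage-like cells, where the highest other was 2659 in a near mirror of the real grouping. Chance cannot be excluded for the 2 Treg-like calls (4 of 30 splits, highest other 4) or the 19 neutrophil-like ones (2 of 35, highest other 23). A real 0, which every split reaches, was again untested for CPV NR against CP, with 100 of 100, 60 of 60, 100 of 100 and 35 of 35 splits of CD8 T-like, Treg-like, monocyte/macrophage-like and neutrophil-like cells (highest other 11, 4, 148 and 0), and for CPV R against CPV NR, with 60 of 60 splits of each (highest other 0, 1, 1 and 1). For CP against untreated 10 splits are too few: 10 reached the real 0 in CD8 T-like cells (highest other 10) and 1 the real 318 in monocyte/macrophage-like cells (highest other 259).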

How the results depend on the processing

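Of 654 alternatives to the numbers of changed genes, 425 were within 1.5 times and 229 moved; the cause was not tested. With DESeq2, the anti-VISTA R against IgG counts were 22 (CD8 T-like), 1 (Treg-like) and 890 (monocyte/macrophage-like). CP against untreated gave 10, 513 and 36 (CD8 T-like, monocyte/macrophage-like, neutrophil-like). CPV R against CP gave 191 (CD8 T-like) and 56 (neutrophil-like), CPV NR against CP 7, 2 and 101 (CD8 T-like, Treg-like, monocyte/macrophage-like), and CPV R against CPV NR 10, 378 and 18 (CD8 T-like, monocyte/macrophage-like, neutrophil-like). With no filter on low counts, anti-VISTA R against IgG gave 9, 53 and 166 (CD8 T-like, Treg-like, neutrophil-like) and CP against untreated 211 and 64 (CD8 T-like, neutrophil-like). CPV R against CP gave 510, 17 and 86 (CD8 T-like, Treg-like, neutrophil-like). CPV NR against CP gave 116, 21, 38 and 28 and CPV R against CPV NR 242, 13, 83 and 62 (CD8 T-like, Treg-like, monocyte/macrophage-like, neutrophil-like). With the replicate block, counts were 4, 11 and 34 for anti-VISTA R against IgG (CD8 T-like, Treg-like, monocyte/macrophage-like), 7, 191 and 30 for CP against untreated (CD8 T-like, monocyte/macrophage-like, neutrophil-like), 15 and 4 for CPV R against CP (CD8 T-like, Treg-like), 9, 3 and 4 for CPV NR against CP (CD8 T-like, Treg-like, neutrophil-like), and 2 and 10 for CPV R against CPV NR (Treg-like, neutrophil-like). With only 2 groups in the fit they were 69 and 240 for CP against untreated (monocyte/macrophage-like, neutrophil-like), 41, 1 and 0 for CPV R against CP (CD8 T-like, Treg-like, neutrophil-like), 2 for CPV NR against CP (CD8 T-like) and 1, 1, 26 and 1 for CPV R against CPV NR. Experiment 1 alone gave 115 for CP against untreated and 0 for CPV R against CP in monocyte/macrophage-like cells, 0 for CPV R against CP in CD8 T-like cells and 9 for CPV R against CPV NR in Treg-like cells. Experiment 2 alone gave 3 for CPV R against CP (neutrophil-like) and 4, 1 and 10 for CPV NR against CP (CD8 T-like, Treg-like, monocyte/macrophage-like). Resolution 2.0 gave 184 for anti-VISTA R against IgG (monocyte/macrophage-like) and 1 for CPV NR against CP (Treg-like). The stricter cell filter gave 55 for anti-VISTA R against IgG (neutrophil-like), 60, 0 and 3 for CPV R against CP (CD8 T-like, Treg-like, neutrophil-like), 1 for CPV NR against CP and 1 for CPV R against CPV NR (both CD8 T-like). Keeping doublets gave 1 for CPV R against CP (Treg-like). Thinned libraries gave 159 and 2 for CP against untreated (monocyte/macrophage-like, neutrophil-like), 1 and 3 for CPV R against CP (Treg-like, neutrophil-like) and 3 for CPV R against CPV NR (neutrophil-like). Single libraries left out gave, for CD8 T-like, Treg-like, monocyte/macrophage-like and neutrophil-like cells, 0 to 2, 0 to 22, 9 to 815 and 27 to 164 for anti-VISTA R against IgG. They gave 0 to 98, 0 to 4, 1627 to 3274 and 2 to 72 for CPV R against CP, 0 to 3, 0 to 2, 0 to 12 and 0 to 0 for CPV NR against CP, and 0 to 1, 0 to 0, 0 to 141 and 0 to 4 for CPV R against CPV NR. CP against untreated gave 0 to 8, 137 to 493 and 3 to 41 (CD8 T-like, monocyte/macrophage-like, neutrophil-like). Classes whose share passed numbered 0 in each experiment and the replicate block for CPV R against CP (0 to 4 leaving out single libraries). For CPV NR against CP they numbered 3 with the stricter filter and 0 in each experiment, the replicate block and limma (0 to 2). The smallest exact p possible was 0.1 in experiment 1, 0.0286 in experiment 2 and 0.0625 in the replicate block, so that these counts of 0 say little. Called lists fell to 0 with the estimated correlation and with fry for anti-VISTA R against IgG, CP against untreated and CPV R against CPV NR, to 1 and 17 for CPV R against CP and to 1 and 0 for CPV NR against CP. Of the single-gene alternatives, 5403 were the same, 749 weaker, 77 stronger and 2 reversed: Pdcd1 in cDC2-like cells of CP against untreated (0.0414 without experiment 1 untreated replicate 2, and between -2.83 and 0.0414 with each library left out) and Ctla4 in NK-like cells of CPV R against CP (0.0870 in experiment 1 alone). Of 144 named passing genes 53 passed in every leave-one-out. Of the alternatives to genes of single libraries 171 were the same, 338 moved and 1 reversed. Of those to lists 881 were the same, 98 moved and 13 reversed. Within CD8 T-like clusters 55 of 60 gene values moved and 1 reversed, and within neutrophil-like clusters all 10 moved. Sorted values that reversed, within CD8 T-like clusters, were cytotoxic effector 0.15, T cell exhaustion 0.19, TCR activation 0.0916 and markers of monocyte/macrophage 0.22 in AH1 monotherapy NR vs IgG; markers of NK 0.00866 and Ass1 -0.0405 in AH1 monotherapy R2 vs IgG; proliferation -0.0608 in AH1 combination CPV NR vs CP; and type I interferon response -0.43 and markers of monocyte/macrophage -0.42 in AH1 combination CPV R vs CP. With genes of at least 10 CPM they were type I interferon response -0.0268 in AH1 monotherapy R1 vs IgG and markers of monocyte/macrophage -0.37 in AH1 combination CP vs untreated. Within neutrophil-like clusters of Ly6G monotherapy anti-VISTA vs IgG they were MHC class II presentation -0.17, myeloid suppression -0.0513 and hypoxia and glycolysis -0.12. Alternatives in which a group had under 2 libraries with 20 cells gave no value; all alternatives named before the data were examined were run.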

Other observations

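Natural killer cells, innate killers of tumour cells, were tested as a further class in CPV R against CP. In NK-like cells 46 genes rose and 8 fell. Sgk1 (ENSMUSG00000019970), a stress-induced kinase, rose by 1.72 ± 0.28 (edgeR adjusted p = 0.00265), Cd74 (ENSMUSG00000024610), the class II invariant chain, by 1.81 ± 0.42 (adjusted p = 0.0376) and Gbp5 (ENSMUSG00000105504), an interferon-induced GTPase, by 1.28 ± 0.25 (adjusted p = 0.0140). Tysnd1 changed by -1.18 ± 0.28 and Lonp1 (ENSMUSG00000041168), a mitochondrial protease, by -0.88 ± 0.20. These lay on their side in all 7 CP libraries too. All 24 type I interferon genes were positive (median 0.65, 1 passing and 10 adjusted within the list; camera adjusted p = 2.33e-09, adjusted p = 0.191 at estimated correlation). The total of 54 was 34 without experiment 1 CP replicate 1, 13 without experiment 1 CPV R replicate 2, 33 and 17 without experiment 2 CPV R replicate 1 or 3, and 26 and 22 without experiment 2 CP replicate 3 or 4. Experiment 1 alone gave 1 and experiment 2 alone 90, no filter on low counts 242, the replicate block 27 and thinned libraries 8.

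In cDC2-like cells of monotherapy experiment 2, which present antigen to CD4 T cells, Stmn1 (ENSMUSG00000028832), a tubulin regulator of dividing cells, rose by 2.12 ± 0.32 (edgeR adjusted p = 0.0189) and Tk1 (ENSMUSG00000025574), thymidine kinase, by 3.19 ± 0.56 (adjusted p = 0.0477), while Pgf (ENSMUSG00000004791), an angiogenic factor, changed by -1.54 ± 0.22. All 21 proliferation genes were positive there (median 0.91, 2 passing and 11 adjusted within the list; camera adjusted p = 3.03e-25, adjusted p = 0.142 at estimated correlation). The 7 calls became 1, 2 and 0 without IgG replicate 1, 2 or 3 and 5, 15, 2, 4 and 7 without R replicate 1, 2, 3, 4 or 5, and were 23 with DESeq2, 88 with no filter on low counts, 32 with doublets kept, 20 with the replicate block and 1 with the stricter cell filter.

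Interferon response genes were higher in macrophages of CPV R than of CP tumours. Between R and NR edgeR called 0 genes there (2442 at an unadjusted p under 0.05), DESeq2 378, and edgeR 141 without experiment 1 CPV R replicate 1. The list score of type I interferon genes in monocyte/macrophage-like cells was 7.49 ± 0.725 in CPV R, 6.81 ± 0.280 in CPV NR (SD, n = 5 each) and 6.44 ± 0.382 in CP (SD, n = 7). R and NR differed by 0.68 (exact permutation p = 0.0333), a test chosen after the result was seen. Experiment 2 CPV R replicate 3 carried much of this, with a score of 8.67 against 6.76 to 7.62 in the other 4 R libraries. Without it the difference was 0.43 (exact p = 0.05), and with each other library left out the exact p lay between 0.0167 and 0.0833, with 60 groupings that allow none below 0.0167. Whether the interferon rise goes with response may therefore rest on few tumours, the R against NR median of all libraries being 0.75, and neither order nor cause was tested.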
